A study of Homo sapiens with 4 samples.

How the data were processed

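The deposited table held read counts and FPKM per gene for 4 libraries, 1 per group. Per the authors' notes, counts were made by aligning reads to GRCh38 with HISAT2, whose version is not given in the sources used here, and counting them per gene with HTSeq 0.13.5. Per the file headers the deposited FPKM values are fragments per kilobase scaled to library size, and dividing the authors' counts by them gave gene lengths that were whole to within 0.01 base for 100% of the values checked. The annotation release and the strand setting of the count step are not given in the sources used here, so counts of genes that overlap another gene are uncertain. Per the labels, cells were selected with 0.5 µg/ml puromycin and 600 µg/ml G418, 72 h of doxycycline is given for the Western blot, and 1.5 µg of RNA went into each NEBNext library.

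The table listed 24940 genes, of which 14791 are protein-coding in GENCODE 29, and 0 had no count in every library. All 24940 identifiers are in GENCODE 29, 24929 under the same name, and 25 symbols occur more than once. Genes with a count numbered 19450 in shControl, 19823 in sh-Bcl2, 21426 in sh-c-Myc and 20318 in the double knockdown. TMM factors were 0.950, 0.965, 1.08 and 1.01 in that order, and 3 counts, the floor for bounds, correspond to 0.202, 0.191, 0.208 and 0.194 CPM. Cytosolic ribosomal protein genes took 8.97%, 7.13%, 5.75% and 6.14% of counts.

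The following choices were made before the data were examined: the groups, the comparisons, the gene lists, the rule for named genes, the thresholds and every alternative setting except the removal of a GC and length trend and the rescaling of the share of the sh-c-Myc change that the double knockdown regained. The comparisons are each knockdown library against shControl, the double knockdown against each single knockdown, and the departure of the double knockdown from the sum of the single knockdowns. With 1 library per group no test between 2 groups is possible, so log2 ratios of TMM-scaled counts (prior 0.5) are given with exact conditional binomial 95% intervals, which cover counting error and not the spread between cultures. A gene was called higher or lower when the ratio was at least 2-fold, the interval excluded a ratio of 1, and at least 1 library held at least 1 CPM, which 13726 genes met. The departure is the log2 ratio of the double knockdown minus those of both single knockdowns, with a delta-method interval. For calls without an effect, 100 draws of libraries over the same 13726 genes were simulated at the observed depths, with counting error and the common dispersion of the 2 by 2 fit (0.0221), which holds the non-additive part as well.

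The 2 by 2 layout was fitted with edgeR (TMM, quasi-likelihood, 1 term per hairpin) on 12885 genes with at least 1 CPM in at least 2 libraries, with Benjamini-Hochberg adjustment over all of them. The fit has 1 residual degree of freedom, which holds the non-additive part and the spread between libraries together. The common dispersion was 0.0221, a biological coefficient of variation of 0.149, with 11.1 prior degrees of freedom. DESeq2 and limma-voom were run as alternatives.

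A set of 34 gene lists and 8 lists of cell type markers was written from general knowledge. The lists cover complex I, complexes II to V, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, mitochondrial DNA maintenance, mitochondrial import and folding, fission and fusion, mitophagy, the tricarboxylic acid cycle, fatty acid oxidation, antioxidant genes, glycolysis, nucleotide synthesis, ribosome biogenesis, cytosolic ribosomal proteins, the MYC network, both arms of the BCL-2 family, caspases, p53 targets, G1/S, G2/M, cyclin-dependent kinase inhibitors, the integrated stress response, the unfolded protein response, heat shock, interferon, NF-kB, immediate early genes, hypoxia, cholesterol synthesis, HOXA and KMT2A-fusion targets, histones and lysosome. Each list's median log2 ratio over members that met the CPM filter was placed among those of 10000 random lists matched for expression in 20 bins, and it stands apart below the 2.5th or above the 97.5th percentile. For the 2 by 2 fit, counts are given over all genes tested and adjusted over the list alone.

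Genes named in the text are MYC and BCL2; the 10 per direction with the largest conservative fold (the end of the interval nearest to 1) at 10 CPM or more in each comparison with shControl; up to 4 members of each list; 10 per direction and hairpin that moved the same way in both backgrounds; and the 5 per direction with the largest departure from additivity. A gene outside this rule is said to be so where it is named.

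The methods were run on simulated tables after the real table had been analysed. The 2 by 2 fit recovered 77% of genes changed 2-fold and 99% of those changed 4-fold by the c-Myc hairpin with 7 unchanged genes called, and 81%, 99% and 11 for the Bcl-2 hairpin. These tables gave every gene the same dispersion (0.0221), changed 100 genes at each size by 1 hairpin alone, and held no non-additive part. The real libraries differ in these respects, so the recovered shares need not hold for them. In a separate simulation with counting error alone, the 95% intervals held the true ratio for 95.6% of 13726 genes, and the size rule called 72 unchanged genes, fewer than with the dispersion added, while recovering 93% and 100% of genes with a log2 change of 1.5 and 3. Among random lists with no effect 8.5% of a first 200 stood apart, and 5.42% of the full set of 4000, where 5% would by construction. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.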

Results

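RNA-seq read counts per gene were compared across 4 libraries of MOLM-13, a human acute myeloid leukaemia cell line that carries a KMT2A fusion. The cells carried doxycycline-induced short hairpins against Bcl-2 (sh-Bcl2), against c-Myc (sh-c-Myc) or against both (sh-c-Myc_sh-Bcl2, called the double knockdown here), or a control hairpin (shControl). Each of the 4 groups held 1 library, so differences between groups have no replicate check. The libraries held 14825763 (shControl), 15691129 (sh-Bcl2), 14421558 (sh-c-Myc) and 15494138 (double knockdown) counts over 24940 listed genes. Intervals in brackets are 95% intervals that cover counting error only, except those of the regained shares of gene lists, described where they are given. Levels are library-scaled counts (CPM) with TMM factors, and a gene was called higher or lower by a fixed rule of size: at least 2-fold apart, an interval that excludes a ratio of 1, and at least 1 CPM in at least 1 library.

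The targeted transcripts were examined first. BCL2 (ENSG00000171791, chromosome 18, 63123346 to 63320128 on GRCh38), which encodes the anti-apoptotic protein at the outer mitochondrial membrane, stood at 119.7 CPM in shControl [114.1 to 125.6], 38.7 in sh-Bcl2 [35.6 to 42.0], 112 in sh-c-Myc [106 to 117] and 44.5 in the double knockdown [41.3 to 48.0]. Its log2 ratio to shControl was -1.63 in sh-Bcl2 [-1.77 to -1.49] and -1.43 in the double knockdown [-1.56 to -1.30]. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434 on GRCh38), which encodes the transcription factor, stood at 433.7 CPM in shControl [422.9 to 444.8], 364.3 in sh-Bcl2 [354.7 to 374.0], 278.2 in sh-c-Myc [269.9 to 286.6] and 301.6 in the double knockdown [293.1 to 310.4]. Its log2 ratio to shControl was -0.64 in sh-c-Myc [-0.70 to -0.58], -0.52 in the double knockdown [-0.58 to -0.47] and -0.25 in sh-Bcl2 [-0.30 to -0.20], so no library reached a 2-fold reduction of MYC RNA. With total-count scaling the MYC ratio in sh-c-Myc was -0.45. Protein levels were not analysed here.

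**Figure D1:**
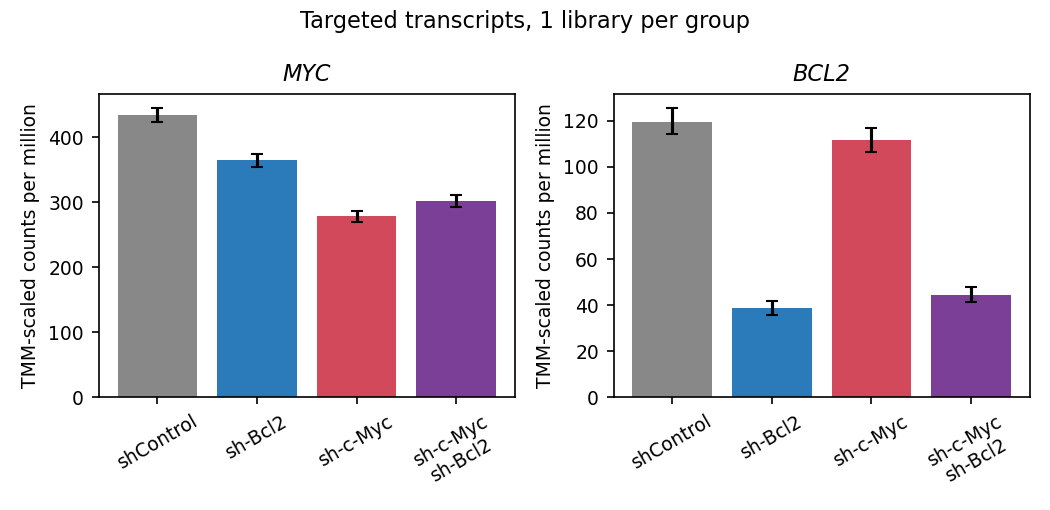
MYC (left) and BCL2 (right) in TMM-scaled CPM (vertical axes from 0) in the 4 libraries, 1 bar per library, with exact 95% Poisson intervals that cover counting error only. BCL2 is lowest in the libraries with the Bcl-2 hairpin (38.7 and 44.5 CPM), and MYC is lowest in those with the c-Myc hairpin (278.2 and 301.6 CPM).

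The library with the c-Myc hairpin alone was compared with shControl to describe the single c-Myc knockdown. Genes of cell division, ribosome production and nucleotide synthesis were lower in sh-c-Myc, and monocyte and granule genes were higher. Of 42 measured genes of DNA replication and G1/S, 36 were lower and 0 higher (median log2 ratio -1.50), among them the replicative helicase gene MCM4 (3.54-fold lower [3.42 to 3.67]) and the cyclin E gene CCNE1 (4.22-fold lower [3.30 to 5.51]). Of 59 genes of ribosome biogenesis 48 were lower (median -1.43), such as MYBBP1A (4.93-fold lower [4.55 to 5.34]) and LYAR (4.66-fold lower [4.02 to 5.46]). Of 19 measured monocyte and macrophage markers 13 were higher (median 2.19): CSF1R, the receptor for macrophage colony-stimulating factor, was 9.43-fold higher [8.33 to 10.8], S100A8 8.42-fold [6.57 to 11.1] and the lysozyme gene LYZ 6.63-fold [6.04 to 7.29].

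Several lists of nuclear genes for mitochondrial proteins had medians below random lists in sh-c-Myc, the lowest of them mitochondrial protein import and folding. Of 29 measured members of that list 15 were lower (median -1.01), including the chaperone genes HSPD1 (3.65-fold lower [3.54 to 3.77]) and TRAP1 (4.21-fold [3.81 to 4.67]) and the import channel gene TOMM40 (3.85-fold [3.54 to 4.18]). Of 76 mitochondrial ribosomal protein genes 21 were lower (median -0.67; MRPL24 at log2 -1.77), and of 21 genes of mitochondrial DNA maintenance and transcription 7 were lower (median -0.56), with TWNK, the mitochondrial helicase, 3.98-fold lower [3.59 to 4.43] and the transcription factor gene TFAM 2.04-fold lower [1.92 to 2.17]. Medians of nuclear respiratory chain genes were -0.41 for complex I (3 of 36 lower, 1 higher) and -0.57 for complexes II to V (3 of 37 lower), of the tricarboxylic acid cycle -0.51, and of fission, fusion and cristae organisation -0.63. With the trend on GC content and length removed, complex I (-0.22), complexes II to V (-0.27) and the tricarboxylic acid cycle (-0.45) lay within random lists. The 13 mitochondrially encoded mRNAs had a median of 0.08, within the range of random lists, and fatty acid oxidation genes one of -0.00. Mitophagy and autophagy genes had a median of 0.42 (1 of 27 higher), and lysosome genes one of 0.39 (6 of 29 higher).

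Other lists moved with these. One-carbon, nucleotide and polyamine synthesis had 21 of 31 members lower (median -1.38; the polyamine enzyme gene ODC1 5.38-fold lower [4.85 to 5.99]), mitosis and G2/M 31 of 44 (median -1.19; CDC20 at log2 -2.17), heat shock and chaperones 12 of 19 (median -1.06), and cytosolic ribosomal proteins 23 of 77 (median -0.81). Glycolysis genes (median -0.56; LDHA at -1.75), antioxidant genes (-0.56; NQO1 at -2.11), the ATF4 and integrated stress response list (-0.72) and pro-apoptotic BCL-2 family genes (-0.57) were also below random lists. Granule genes of granulocytes were higher in 7 of 12 (median 1.39), with the myeloperoxidase gene MPO 4.97-fold higher [4.73 to 5.23] and ELANE 2.53-fold [2.45 to 2.62]. The interferon response list had 8 of 36 members higher and 1 lower (median 0.47, within random lists with FPKM + 1 or with a mean of members), stem and progenitor markers 3 of 10 higher (median 0.54) and replication-dependent histones 10 of 12 higher (median 1.89). Those histones were at most 15.7 CPM in sh-c-Myc (HIST1H2BK), and 35 of the list's 47 genes appear in the table. In the same library lincRNA, antisense and intronic RNAs took 1.04% of counts against 0.596% in shControl and pseudogenes 0.734% against 0.544%, and 21426 genes had a count against 19450. The 5 measured B cell markers had a median of 1.27 (percentile 86.25) and the 3 megakaryocyte markers one of 0.76 (61.44), both within random lists.

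Over 13726 genes, 1745 were higher and 1344 lower in sh-c-Myc, while simulated libraries with no effect gave on average 179 calls over the same genes, with a spread between libraries added to counting error. The genes with the largest conservative fold were CSF1R, CD209, FGL2, S100A8, FGD2, PTAFR, FCER2, RAB37, GPA33 and LYZ among the higher and SLC29A1, EGR1, CDC42EP1, MT2A, NCS1, NKD2, DDN, HPDL, GSTP1 and TNFRSF19 among the lower. The nucleoside transporter gene SLC29A1 was 14.4-fold lower [12.4 to 16.8] and the immediate early gene EGR1 13.9-fold lower [10.6 to 19.0]. The median log2 ratio of genes with a mean of at least 50 counts was -0.10 with TMM scaling and 0.08 with total counts, and the higher share of calls went from 56.5% to 70.9% (70.7% with upper quartile factors), so levels hold relative to that shift. It was 41.0% with a mean of at least 50 counts and 46.0% for protein-coding genes, where lower calls outnumber higher ones. Antioxidant (-0.35) and pro-apoptotic genes (-0.33) also lay within random lists with the GC and length trend removed.

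**Figure D2:**
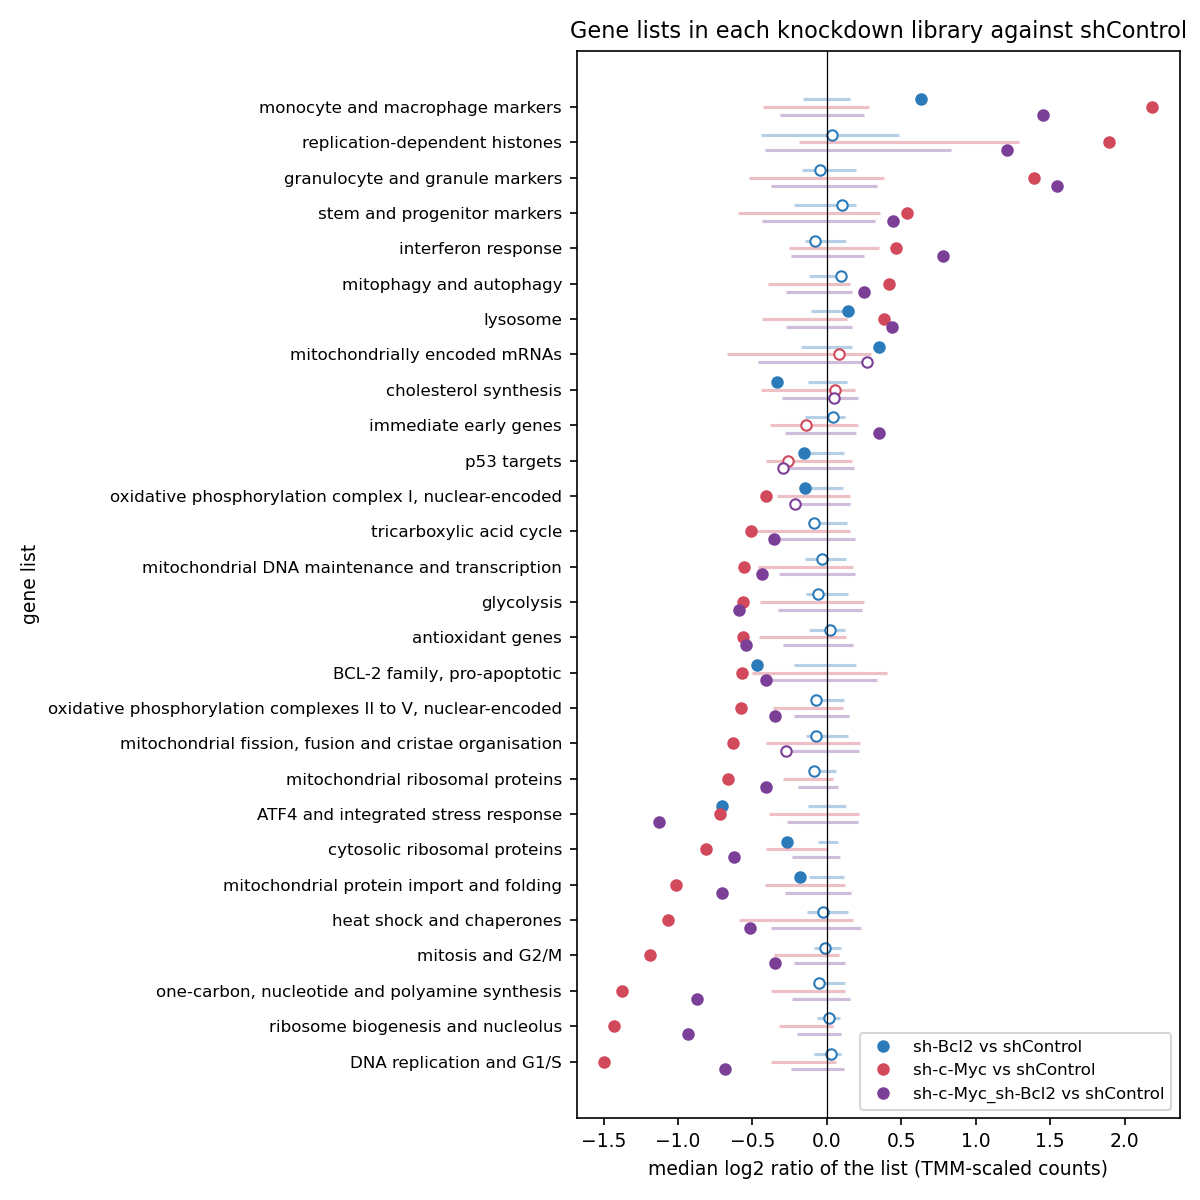
Median log2 ratio (horizontal axis) of each gene list in the 3 knockdown libraries against shControl, with lists that stand apart in at least 1 comparison on the vertical axis. Filled points lie outside the central 95% range of 10000 expression-matched random lists, which the pale lines show, and open points lie inside it.

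The library with the Bcl-2 hairpin alone was compared with shControl to describe the single Bcl-2 knockdown. Fewer genes differed than in sh-c-Myc, and the list that stood lowest was that of ATF4 targets and the integrated stress response. Of its 27 measured members 6 were lower and 0 higher (median -0.70), with SLC7A5, a large neutral amino acid transporter gene, 3.38-fold lower [3.23 to 3.54] and DDIT4, an inhibitor of mTORC1, 2.65-fold lower [2.42 to 2.91]. Monocyte and macrophage markers had 3 of 19 higher (median 0.63), among them LYZ (2.54-fold higher [2.29 to 2.82]). Granule genes had a median of -0.05, with MPO at 164 CPM against 131 in shControl and CTSG 2.38-fold lower. The cytokine gene TNF was 3.74-fold higher [3.12 to 4.53] and the lectin gene CD209 3.84-fold higher [2.76 to 5.54].

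Mitochondrially encoded mRNAs had a median of 0.35 in sh-Bcl2, above random lists, with 0 of 13 members 2-fold apart and MT-ND4 1.43-fold higher [1.41 to 1.44]. All listed genes of the mitochondrial chromosome together held 5.60% of counts in this library, 4.53% in shControl, 5.80% in sh-c-Myc and 5.73% in the double knockdown. Mitochondrial import genes had a median of -0.18 (2 of 29 lower; TIMM10 2.12-fold lower [1.79 to 2.52]), and complex I genes one of -0.14 (0 of 36). Medians of complexes II to V (-0.07), mitochondrial ribosomal proteins (-0.09), mitochondrial DNA maintenance (-0.03), fission and fusion (-0.07), mitophagy (0.10), the tricarboxylic acid cycle (-0.09) and fatty acid oxidation (-0.00) lay within random lists. Pro-apoptotic BCL-2 family genes had a median of -0.47, with BBC3, which encodes PUMA, 2.29-fold lower [1.82 to 2.92]. Cytosolic ribosomal proteins (median -0.27; RPL36 at log2 -1.25), cholesterol synthesis (-0.33) and p53 targets (-0.15) were below random lists, and lysosome genes (0.14) above them, though means of the p53 targets (-0.15) and lysosome genes (0.09) lay within.

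Over the same 13726 genes, 337 were higher and 296 lower, against 181 calls on average in libraries simulated in that way. The rule for named genes gave CD209, CHI3L1, CYP19A1, CYP46A1, FCER2, LYZ, MYBPH, NAV3, TNF and TRAC among the higher and BCL2, DDIT4, FKBP2, LNPK, MEX3A, NUDT1, PFDN2, PFDN6, RPL36 and SLC7A5 among the lower. In this comparison log2 ratios fell with transcript GC content (Spearman rho across 10023 genes -0.37). The trend followed the Bcl-2 hairpin: rho was -0.34 in the double knockdown against sh-c-Myc and -0.21 against shControl, but -0.001 in sh-c-Myc against shControl and -0.02 in the double knockdown against sh-Bcl2. With that trend removed 66.0% of calls were higher, against 53.2%, and the complex I median was -0.02. With the trend left in, the higher share was 47.2% for protein-coding genes and 44.9% at 1.5-fold, where lower calls outnumber higher ones. DDIT4 shares 41.2% of its exonic bases with another gene, and LYZ 34%. Counts of both are uncertain in every library because the counting settings are not given in the sources used here.

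The double knockdown was compared with shControl and with each single knockdown. Against shControl the integrated stress response list was lower than in either single knockdown library: 16 of 27 members were lower (median -1.13). The stanniocalcin gene STC2 was 11.8-fold lower [8.80 to 16.5], SLC7A5 7.39-fold lower [6.96 to 7.87] and CHAC1, a glutathione-degrading enzyme gene, 7.09-fold lower [4.91 to 10.9]. Myeloid genes were higher, with 13 of 19 monocyte markers (median 1.45; LYZ 9.58-fold [8.76 to 10.5], CSF1R at 152 CPM against 18.9 in shControl) and 8 of 12 granule genes (median 1.54; ELANE 3.58-fold [3.47 to 3.70]). Interferon response genes had 11 of 36 members higher and 0 lower (median 0.78; RSAD2 3.88-fold higher [2.81 to 5.53]).

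Several lists of nuclear mitochondrial genes were lower in the double knockdown, by less than in sh-c-Myc. Import and folding genes had 8 of 29 members lower (median -0.70; HSPD1 2.24-fold lower [2.18 to 2.30]), mitochondrial ribosomal proteins 12 of 76 lower and 1 higher (median -0.41) and mitochondrial DNA maintenance 2 of 21 lower (median -0.44). Medians were -0.35 for complexes II to V, -0.36 for the tricarboxylic acid cycle, -0.22 for complex I (percentile 3.47) and 0.27 for mitochondrially encoded mRNAs (percentile 95.78), the last pair within random lists. Fission, fusion and cristae genes (-0.27, percentile 3.41; 2 of 22 lower) and fatty acid oxidation genes (0.04; 1 of 15 higher) lay within them too. With the GC and length trend removed, complexes II to V (-0.17) and pro-apoptotic genes (-0.29, from -0.41) lay within random lists too. Ribosome biogenesis (24 of 59 lower, median -0.93), nucleotide synthesis (9 of 31, -0.87), cytosolic ribosomal proteins (12 of 77, -0.62), DNA replication and G1/S (4 of 42, -0.68) and mitosis and G2/M (0 of 44, -0.35) stood below random lists, as did glycolysis (-0.59), antioxidant genes (-0.55) and heat shock (-0.52). Lysosome (0.44), mitophagy (0.25), histone (1.21), stem and progenitor (0.44) and immediate early genes (0.35; 4 higher and 4 lower of 29) stood above them, the last not with a mean in place of the median.

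In all, 977 genes were higher and 817 lower than in shControl (476 and 521 with a mean of at least 50 counts), against 176 calls on average in simulated libraries with no effect. The double knockdown shared 769 higher and 561 lower genes with sh-c-Myc, where independent lists would share 124 and 80 and simulated libraries with no effect 20.2 and 11.7. With sh-Bcl2 it shared 195 higher and 120 lower, where independent lists would share 24.0 and 17.6 and simulated libraries 21.1 and 10.7. The libraries sh-Bcl2 and sh-c-Myc, whose targeting hairpins differ, shared 225 higher and 87 lower, where independent lists would share 42.84 and 28.98 and simulated libraries 21.1 and 11.4, so the overlap with sh-Bcl2 does not by itself point to the Bcl-2 hairpin. The covariance of log2 ratios was 0.41 for sh-c-Myc and the double knockdown, 0.12 for sh-Bcl2 and the double knockdown and 0.10 for sh-Bcl2 and sh-c-Myc, against 0.05 in each simulation. The correlations across genes were 0.87, 0.57 and 0.38 in that order, against 0.50 in each simulation, so that of sh-Bcl2 and sh-c-Myc lay below its simulated value. A correlation falls as the ratios of 1 library spread more (SD 0.77 in sh-c-Myc, 0.34 in sh-Bcl2), so it need not mean less sharing. The simulated libraries share 1 control too. A deviation of the real control beyond the simulated spread may still be part of each excess in shared genes and covariance. The rule for named genes added S100A8, S100A9, MPEG1, PTAFR, FGD2, FGL2, FCER2 and CD209 among the higher and CDC42EP1, DDN, EIF4EBP1, NCS1, NKD2, SLC38A1 and ZNF395 among the lower.

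**Figure D3:**
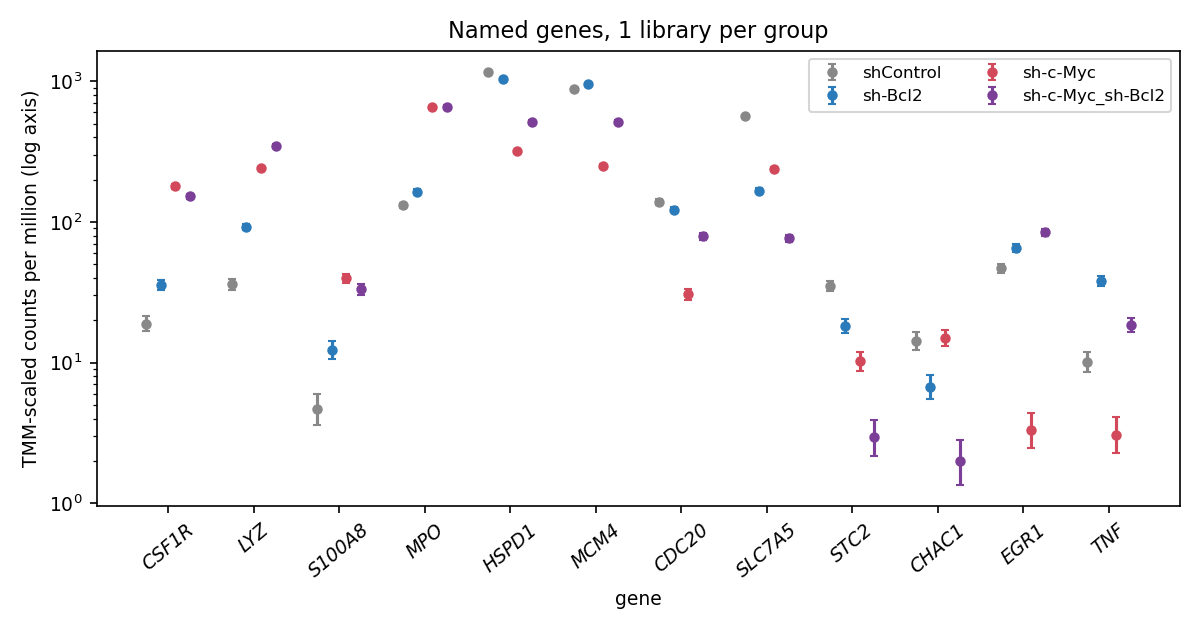
TMM-scaled CPM (log axis) of 12 named genes in the 4 libraries, 1 point per library, with exact 95% Poisson intervals that cover counting error only. CSF1R, LYZ, S100A8 and MPO are higher and HSPD1, MCM4 and CDC20 lower in both libraries with the c-Myc hairpin, SLC7A5 and STC2 are lowest in the double knockdown, and EGR1 is lowest in sh-c-Myc (3.34 CPM).

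Adding the Bcl-2 hairpin to the c-Myc hairpin went with higher cell cycle genes and a lower stress response list. Against sh-c-Myc, the double knockdown had 10 of 42 G1/S genes (median 0.82; CDC6 2.49-fold higher [2.20 to 2.83]) and 11 of 44 G2/M genes (median 0.87; CDC20 2.57-fold [2.31 to 2.86]) higher and 0 lower. In sh-Bcl2 against shControl the same lists had medians of 0.03 and -0.01, within random lists. There 0 of 42 and 0 of 44 members were at least 1.5-fold apart with an interval that excludes a ratio of 1. The lowest G2/M member stood at log2 -0.79, without such an interval. ODC1 was 3.08-fold higher [2.77 to 3.44], and EGR1 25.1-fold higher [19.2 to 34.1], from 3.34 to 84.5 CPM. SLC7A5 was 3.10-fold lower [2.91 to 3.32], CHAC1 7.50-fold [5.21 to 11.4] and STC2 3.46-fold, and the stress response list had 5 of 27 members lower (median -0.33). Medians of mitochondrial import (0.33), mitochondrial ribosomal proteins (0.26), mitochondrial DNA maintenance (0.28), ribosome biogenesis (0.54), nucleotide synthesis (0.50), heat shock (0.50), endoplasmic reticulum unfolded protein response (0.38) and interferon genes (0.24) were above random lists. Those of monocyte markers (-0.23; ITGAX 2.43-fold lower [2.25 to 2.62]), mitophagy (-0.06) and p53 targets (-0.09) were below. In total 227 genes were higher and 666 lower, and 108 and 105 among genes with a mean of at least 50 counts, so the excess of lower calls is not seen among those. Mitochondrial DNA maintenance (0.15) and p53 targets (-0.03) lay within random lists once the GC and length trend was removed, as did the mean of monocyte markers (-0.11) and the interferon median over genes with a mean of at least 50 counts (0.20).

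Adding the c-Myc hairpin to the Bcl-2 hairpin went with higher myeloid genes and lower growth genes. Against sh-Bcl2, the double knockdown had 9 of 19 monocyte markers higher (median 0.82; CSF1R 4.25-fold [3.87 to 4.68]) and 8 of 12 granule genes (median 1.39; MPO 4.03-fold [3.85 to 4.21]). Ribosome biogenesis genes were lower in 22 of 59 (median -0.93; PUS7 3.32-fold lower [2.91 to 3.82]), nucleotide synthesis in 8 of 31 (median -0.73), the stress response list in 7 of 27 (median -0.48; STC2 6.14-fold lower [4.52 to 8.66]) and mitochondrial import in 3 of 29 (median -0.48; TRAP1 2.41-fold lower [2.21 to 2.63]). HMOX1, the haem-degrading enzyme gene, was 5.75-fold lower [4.49 to 7.54]. Medians of G1/S (-0.71), G2/M (-0.31), mitochondrial ribosomal proteins (-0.36), mitochondrial DNA maintenance (-0.42), glycolysis (-0.47), antioxidant genes (-0.49), heat shock (-0.54), cytosolic ribosomal proteins (-0.29) and complexes II to V (-0.20, or -0.13 and within random lists with the trend removed) were below random lists. Interferon (0.69), histone (1.01), lysosome (0.37), mitophagy (0.23), cholesterol synthesis (0.35) and stem and progenitor genes (0.43) were above them. In total 714 genes were higher and 494 lower.

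The departure of the double knockdown from the sum of the 2 single knockdowns was computed per gene on the log2 scale. It was positive for cell cycle and growth genes, that is, the double knockdown was less low than the sum. G2/M genes had a median of 0.84 (13 of 44 past the size rule), G1/S genes 0.83 (10 of 42), nucleotide synthesis 0.58, heat shock 0.51, cytosolic ribosomal proteins 0.50, ribosome biogenesis 0.50, mitochondrial import 0.48 and mitochondrial ribosomal proteins 0.33. Immediate early genes, which were above random lists in the double knockdown against shControl, had a departure of 0.41. It was negative for monocyte markers (median -0.85; 9 of 19 past the rule in that direction and 1 in the other), mitochondrially encoded mRNAs (-0.21), mitophagy (-0.14) and lysosome genes (-0.09). The stress response list had a median of 0.18, within random lists, and SLC7A5 departed by 0.12. Among single genes EGR1 departed by 4.17 [3.75 to 4.59], the metallothionein gene MT2A by 3.62 [2.68 to 4.56], MEX3A by 2.10, HIRIP3 by 1.82 and NUDT1 by 1.80, and in the other direction ADAM28 by -2.62 [-3.19 to -2.05], CHI3L1 by -2.12 [-2.20 to -2.04], LINC01268 by -1.87, IL12A-AS1 by -1.83 and MYBPH by -1.80.

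Positive departures past the rule numbered 414 and negative ones 801, a positive share of 34.1%. That share was 22.3% with total counts and 20.9% with upper quartile factors, 46.6% with a mean of at least 50 counts, 46.7% for protein-coding genes and 51.5% at 1.5-fold, where the balance turns. Medians of interferon (0.24), cholesterol synthesis (0.32), pro-apoptotic (0.39), tricarboxylic acid cycle (0.31), complex I (0.28), complexes II to V (0.24) and fission and fusion genes (0.35) were above random lists, each but the interferon and cholesterol lists within them once the GC and length trend was removed. The interferon median lay within them over genes with a mean of at least 50 counts (0.20), and so did the mean of the cholesterol list (0.31). Stem and progenitor markers had a median of -0.20 and a mean of 0.02, which differ in sign.

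Both hairpins were also tested over all 4 libraries as a 2 by 2 layout, in which each hairpin's effect is seen in 2 backgrounds that share no library. These are not replicates of a group, and the 1 residual degree of freedom holds the non-additive part and the spread between libraries together. Disagreement between the backgrounds thus counts against a call, so the same sign in both among called genes is largely built into the test. For the c-Myc hairpin, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called 3021 of 12885 genes, 1186 higher and 1835 lower, each with the same sign in both backgrounds. Lower genes took in 58 of 59 ribosome biogenesis genes (59 adjusted over the list alone), 38 of 42 G1/S genes (42), 29 of 44 G2/M genes (38), 27 of 31 nucleotide synthesis genes (29), 19 of 29 mitochondrial import genes (23), 32 of 76 mitochondrial ribosomal proteins (43), 11 of 21 mitochondrial DNA maintenance genes (11), 28 of 77 cytosolic ribosomal proteins (37), 14 of 19 heat shock genes (14) and 11 of 27 stress response genes (16). Of the respiratory chain, 6 of 36 complex I genes (6) and 9 of 37 of complexes II to V (13) fell. Higher genes took in 13 of 18 monocyte markers (13), 7 of 11 granule genes (7), 12 of 32 interferon genes (13, with 1 lower), 9 of 29 lysosome genes (11), 9 of 27 mitophagy genes (9) and 6 of 9 histones (7). By edgeR the smallest adjusted p among the named genes was 1.05e-05, for CDC42EP1 (log2 ratios -3.69 and -3.24 in the 2 backgrounds), and that of MYC itself was 0.0793.

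By the rule for genes moved in both backgrounds, CBX7, CXCL16, DOCK3, GGT5, GPA33, IQCN, RHPN1, SIGLEC1, TENM3 and ZBED9 rose with the c-Myc hairpin, and CDC42EP1, DDN, HPDL, IL12A, NCS1, NKD2, PRDM13, SLC29A1, SLC7A2 and SLC7A5P1 fell. SIGLEC1, a macrophage adhesion receptor gene, was at 0.071 CPM in shControl, 0.132 in sh-Bcl2, 5.96 in sh-c-Myc and 7.29 in the double knockdown. SLC7A5P1 is a processed copy of SLC7A5 and may take reads from it.

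For the Bcl-2 hairpin the same test called 5 genes, 2 higher and 3 lower, with 967 below an unadjusted p of 0.05. SLC7A5 (edgeR adjusted p 0.00316; log2 ratios -1.76 and -1.63), BCL2 (0.0055; -1.63 and -1.32) and ADAM9, a metalloprotease gene (0.0492; -1.25 and -0.99), fell, and TNF (0.0055; 1.90 and 2.57) and SPP1, the osteopontin gene (0.0353; 2.84 and 2.23), rose. ADAM9 lies outside the rule for named genes and is named because it completes the 5. Adjusted over the list alone, 12 of 27 stress response genes fell, against 1 over all genes tested. By size in both backgrounds, ACRV1, CLEC5A, EGOT, OLR1, PTMAP5, PTX3, RIMBP3C and RTL3 were also higher and C1R, CEACAM19, DOCK3, EBF4, ELFN2, INHBE, JAG2, MC1R and SLC9A5 lower with the Bcl-2 hairpin, all at levels under 4 CPM in every library. DESeq2 called 13 genes, limma-voom 3, and edgeR without the c-Myc term 0, with 85 below an unadjusted p of 0.05. Without that term the c-Myc effect goes into the residual, which by itself lowers the calls.

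Across 10739 genes with a mean of at least 50 counts, the c-Myc hairpin's log2 ratios in the 2 backgrounds had a Pearson r of 0.80 and a Spearman rho of 0.78, with a slope of 0.52, and the Bcl-2 hairpin's had an r of 0.14 and a rho of 0.15, or an r of 0.07 with the GC and length trend removed. These correlations are across genes, which are not independent replicates. Of 3089 genes called in sh-c-Myc, 87.9% had the same sign in the other background, and of 633 called in sh-Bcl2, 56.9% did.

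**Figure D4:**
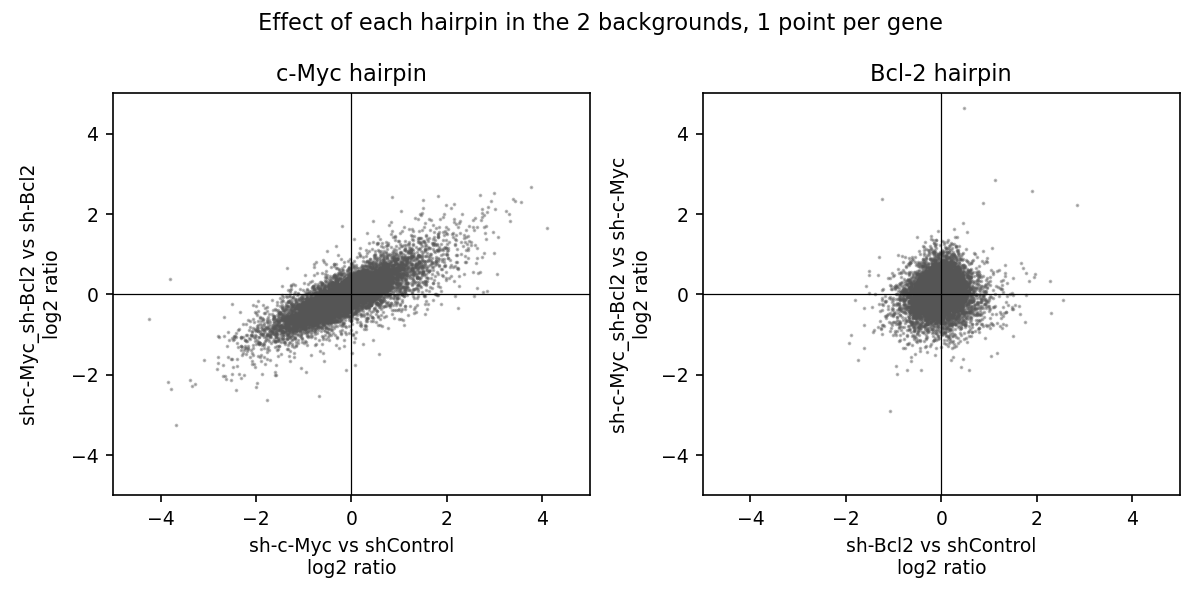
Log2 ratio of each gene with a mean of at least 50 counts, for the c-Myc hairpin (left) and the Bcl-2 hairpin (right), in cells without the other hairpin (horizontal axes) and with it (vertical axes), 1 point per gene, with 1 gene of the left panel outside the axes. The 10739 genes follow a slope of 0.52 for c-Myc (r 0.80) and scatter for Bcl-2 (r 0.14, or 0.07 with the GC and length trend removed).

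The lists in this paragraph gave medians within random lists in the 3 comparisons with shControl, unlike the pro-apoptotic BCL-2 family (-0.47, -0.57 and -0.41 in sh-Bcl2, sh-c-Myc and the double knockdown, each below them). With the GC and length trend removed, the pro-apoptotic medians in sh-c-Myc and the double knockdown lay within random lists. For the HOXA cluster and KMT2A-fusion targets the medians were 0.07 in sh-Bcl2, 0.01 in sh-c-Myc and -0.05 in the double knockdown, and for the caspases and intrinsic apoptosis -0.06, -0.01 and -0.12. The anti-apoptotic BCL-2 family gave -0.21, 0.07 and 0.13, with BCL2A1 at 1.77, 4.89, 5.90 and 5.95 CPM in shControl, sh-Bcl2, sh-c-Myc and the double knockdown. The MYC network gave -0.12, -0.01 and -0.18, NF-kB and inflammatory genes 0.11, -0.07 and 0.20, hypoxia genes -0.06, -0.21 and -0.18, cyclin-dependent kinase inhibitors -0.17, -0.19 and -0.07, and the endoplasmic reticulum unfolded protein response 0.02, -0.20 and 0.12. A median within random lists does not mean that no member moved. In sh-c-Myc 6 of 22 MYC network members were lower and 1 higher, with log2 ratios from -1.755 to 1.956. T and NK cell markers (4 measured) gave -0.07, -0.16 and -0.07. Erythroid and epithelial or fibroblast lists had 2 measured members each and were not described.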

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

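All tests of explanations in this part were chosen only after the result was seen. These results drew attention because the Bcl-2 hairpin went with opposite directions in the 2 backgrounds, and none of these differences was tested, since each group holds 1 library. Mitochondrial protein import and folding genes had a median log2 ratio of -0.1783 when the Bcl-2 hairpin was added to control cells and 0.3285 when it was added to the c-Myc hairpin, and monocyte and macrophage markers 0.6348 and -0.2304. Among single genes ADAM28 stood at 1.161 and -1.459, BLNK at -1.592 and 1.328, and MT2A at -1.234 and 2.386. PADI4, with 0, 7, 58 and 11 counts in shControl, sh-Bcl2, sh-c-Myc and the double knockdown, was at least 1.119 higher on the log2 scale against the floor of 3 counts and then stood at -2.35. In all, 50 genes were called in opposite directions for the Bcl-2 hairpin and 67 in the same direction, against 13 and 776 for the c-Myc hairpin.

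The integrated stress response list was lower in both libraries with the Bcl-2 hairpin than in the matched library without it. The tables argue against a trend on GC content and length as the whole cause: with that trend removed the median was -0.5303 in sh-Bcl2 against shControl and -0.2939 in the double knockdown against sh-c-Myc for the list named ATF4 and integrated stress response, and both still stood apart from random lists. They also argue against a single deviant library, since the double knockdown against sh-c-Myc, which shares no library with the other comparison, gave a median of -0.3276 that stands apart too. No biological explanation was tested. An effect of the Bcl-2 hairpin and a difference in culture between the libraries with and without it both stay open.

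Cell cycle genes were less low in the double knockdown than in sh-c-Myc. One technical explanation is a share of cells in the double knockdown that kept control levels, which would bring all lists back by the same share. Shares are medians over list members at least 1.5-fold apart in sh-c-Myc, a filter on the same library whose change sets the share. Brackets of list shares are bootstrap intervals over those members, which treat genes as independent and hold no spread between cultures. The share needed was 59.95% for 41 of 44 G2/M genes [51.9 to 70.8] and 23.8% for 58 of 59 ribosome biogenesis genes [21.3 to 26.4]. Within these intervals 1 common share could not give both, but spread between cultures could widen them. A first comparison, of G1/S genes (40.4% [35.7 to 45.8]) with granule genes (2.95% [-40.9 to 51.9]), had been undecided and was replaced, after that result, by the highest and lowest of 6 lists with at least 20 members. Shares for nucleotide synthesis, mitochondrial import and mitochondrial ribosomal proteins were 27.4%, 25.9% and 24.6%. They rest on 26 of 31, 23 of 29 and 44 of 76 measured members, in that order. A trend on GC content and length as the whole cause is argued against by a G1/S median of 0.7809 with the trend removed. Weaker knockdown of c-Myc in the double knockdown stays open. MYC RNA regained 15.08% of its loss ([7.81 to 22] from counting error alone), 3.21% with total counts and 5.13% with upper quartile factors. Each lay below the bootstrap interval of the G1/S share. Target genes need not follow MYC RNA in proportion, and the protein was not measured here, so RNA alone does not decide it. A biological effect of BCL2 loss on the cycling of c-Myc knockdown cells was not tested and stays open beside it. A difference in culture between sh-c-Myc and the double knockdown, with 1 library each, stays open as well.

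Monocyte markers were higher in sh-c-Myc. Blood monocytes mixed into the library were considered through 5 transcripts abundant in them (CD14, FCN1, VCAN, S100A12 and HLA-DRA), whose gain came to 0.408% of the gain of CSF1R (160 CPM). Those 5 were picked after their low levels were seen, so a small gain was fixed by the choice. The comparison shows only that these 5 gained little beside CSF1R, and it does not decide whether blood monocytes were mixed in. Cells of other types were not tested. An even background of genomic DNA is argued against because the measured markers gained a median of 11.8 FPKM, while 2759 protein-coding genes with at most 3 counts in shControl gained a median of 0.0121 FPKM, and the same genes reached 0.397 at the upper end of their central 95% range. With the GC and length trend removed the median was 2.078, which argues against that trend as the whole cause. No biological explanation was tested, and an effect of the c-Myc hairpin stays open. Of the 30 markers 19 met the CPM filter, so unexpressed members do not enter the median, and CD14 stood at 0.781, 0.793, 1.22 and 0.960 CPM in shControl, sh-Bcl2, sh-c-Myc and the double knockdown.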

How the results depend on the processing

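Alternatives that removed a trend on GC content and transcript length, or that rescaled the regained shares, were chosen after seeing the data, and the others were planned. No paired analysis was possible because the groups share only 1 replicate number, and leaving out a replicate would leave a group empty. Of 240 list medians 113 stood apart, where lists of randomly drawn genes would give 12. Of the 113, 97 stood apart under all alternatives fixed beforehand. The 240 medians come from the same 4 libraries, and genes of a list can move together, so the excess over 12 is not a test. Over all settings 1589 list values kept their place, standing apart on the same side or lying within random lists as before. A change of sign within random lists was not counted. Of the other values 36 no longer stood apart, 42 newly did, and 1 that had stood apart changed sign: stem and progenitor markers, departure from additivity, with a mean of members of 0.01939. The cause was not tested for these.

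Counts of genes are given as higher then lower. Stricter or looser thresholds and filters change counts by construction. With a mean of at least 50 counts they were 86 and 77 in sh-Bcl2, 768 higher in sh-c-Myc, 476 and 521 in the double knockdown, 108 and 105 for the double knockdown against sh-c-Myc, 292 and 269 against sh-Bcl2, and 236 and 270 for non-additive genes. In the same order of comparisons, 1.5-fold gave 625 and 768; 2737 and 2802; 1833 and 2030; 813 and 1262; 1459 and 1444; 1358 and 1281. A 4-fold limit gave 76 and 59, then 500 and 189, 249 and 122, 32 and 105, 154 and 74, 71 and 288. With the whole interval past 2-fold they were 51 and 57, then 742 and 785, 347 and 320, 42 and 79, 199 and 145, 77 and 153. Protein-coding genes alone gave 178 higher in sh-Bcl2, 1031 in sh-c-Myc, 644 in the double knockdown and 474 for it against sh-Bcl2, 302 lower against sh-c-Myc and 381 negative departures. No filter on low counts gave 1003 lower for the double knockdown against sh-c-Myc.

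With the authors' FPKM + 1 the counts were 49 and 51, then 789 and 553, 337 and 256, 32 and 125, 181 and 117, 84 and 291, as a pseudocount of 1 shrinks ratios of low genes. With FPKM + 0.1 sh-c-Myc had 857 lower and the double knockdown against sh-c-Myc 127 higher, and upper quartile factors gave 273 positive departures; the cause was not tested. Every other count stayed within 1.5 times the reported one.

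MYC in sh-c-Myc stood at log2 -0.4548 with total counts, -0.4586 with upper quartile factors, -0.451 with FPKM + 1 and -0.4544 with FPKM + 0.1, and in the double knockdown at -0.4377, -0.4312, -0.4341 and -0.4374. BCL2 with FPKM + 1 stood at -1.354 in sh-Bcl2 and -1.147 in the double knockdown. The direction held in each. For MYC, total counts and FPKM leave out the TMM factors and upper quartile factors replace them, and for BCL2 a pseudocount of 1 shrinks the ratio. Regained shares of the compared lists stayed within their intervals with total counts and upper quartile factors, and that of MYC did not.

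Calls for the c-Myc hairpin in the 2 by 2 fit ranged from 2066 (DESeq2) to 3459 (no filter). For the Bcl-2 hairpin DESeq2 called 10 lower, voom 1 higher, edgeR with DESeq2 factors 1 higher, no filter 22 higher and 36 lower, a mean of at least 50 counts 5 lower and GC and length offsets 5 lower. With the other hairpin left out of the model edgeR called 0 and 0, with 85 at an unadjusted p under 0.05. The c-Myc effect then sits in the residual, which by itself lowers the calls. The crossed split, shControl and the double knockdown against both single knockdowns, gave 0 edgeR calls. At an unadjusted p under 0.05 it gave 2 genes beside a Bcl-2 term and 411 beside a c-Myc term. Beside a Bcl-2 term the c-Myc effect is again in the residual, so the 2 do not measure that split.

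The correlation between backgrounds for the c-Myc hairpin was 0.8624 with at least 500 counts, 0.6382 with at least 10 and 0.8217 with FPKM + 1. For the Bcl-2 hairpin it was 0.2079, 0.08007 and 0.1669, and 0.06661 with the GC and length trend removed. Why was not tested, though counting error is larger at 10 counts.

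Genes with 0 counts in 1 library and a call numbered 16 higher and 2 lower in sh-Bcl2, 42 and 4 in sh-c-Myc, and 34 and 3 in the double knockdown. Valued against a floor of 3 counts, 1, 1 and 1 of these were under 2-fold. The interferon median in sh-Bcl2 went from -0.0824 to -0.0739, and granule medians did not move.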

Other observations

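No test of an explanation is reported in this part, and the genes named were chosen after their values were seen. Of 377 genes called against shControl in the double knockdown alone, 59 were also called against both single knockdown libraries, 25 higher and 34 lower. These comparisons share the double knockdown library, so they are not separate checks, and neither count was set against simulated libraries. TREM2, a microglial and macrophage receptor gene, stood at 1.77, 1.85, 1.48 and 3.84 CPM in shControl, sh-Bcl2, sh-c-Myc and the double knockdown, and the galectin-binding protein gene LGALS3BP at 0.639, 0.529, 1.22 and 3.01. Among the lower, the peptide hormone gene ADM2 stood at 13.1, 6.87, 8.72 and 2.18 CPM, and the transsulphuration enzyme gene CBS at 10.4, 6.34, 6.93 and 2.94.

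Genes of inflammation did not move as a group. In shControl, sh-Bcl2, sh-c-Myc and the double knockdown CXCL8 stood at 11.9, 26.2, 2.95 and 21.4 CPM and TNF at 10.2, 38.0, 3.08 and 18.5, higher with the Bcl-2 hairpin and lower with the c-Myc hairpin. TRAC, a T cell receptor constant gene, stood at 5.39, 18.6, 5.00 and 4.99 CPM, higher in sh-Bcl2 alone.

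Long intergenic, antisense and intronic RNAs took 0.596% of counts in shControl, 0.629% in sh-Bcl2, 1.04% in sh-c-Myc and 0.778% in the double knockdown. MYC RNA in sh-Bcl2 was 84.0% of that in shControl.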
